A study of Mus musculus with 7 samples.

How the data were processed

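ChIP-seq of Mbd3 (Abcam antibody) and Pol II (Santa Cruz antibody) in feeder-free mouse ES cells was read from 7 libraries in 6 groups. Per the labels, knockdown cells were harvested 48 h after transfection with 2 µg of esiRNA, libraries were amplified with 16 PCR cycles, and products of 250 to 450 bp were purified. Replicate numbers exist for wild-type Mbd3 only, and every other group has 1 library. Each library came as a list of aligned reads and a table of read coverage around start sites. In the lists, deposited by the authors as positions of single reads, each line is 1 distinct read sequence with 1 position, so tallies per window are whole-number counts. Reads were aligned with Bowtie, per the submitters' processing notes, which give no version. The tables, as deposited, hold reads per bin scaled by the authors to RPM (reads per library total of 1e6). Multiplied back, 100% of their values were whole to within 0.1 read, and the implied library totals were 2077925, 14785414, 3494642 and 1621348 reads for Mbd3 in wild type 1, wild type 2, Tet1 knockdown and Brg1 knockdown. For Pol II they were 15647855 (EGFP control), 6260916 (Mbd3 knockdown) and 17087129 reads (Brg1 knockdown). The lists held 95.1, 86.7, 97.8, 97.4, 57.4, 73.7 and 66.9% of these totals, since identical sequences were listed once. The genome build is not given in the sources used here, and the largest positions per chromosome fit mm9.

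Start sites were taken from the coverage tables, which hold 36733, and the 22690 named ones on chromosomes 1 to 19 and X were used. Of 18267 accessions, 17971 were matched to a symbol by accession, 213 by symbol and 64 by an older symbol, which gave 17697 genes. For each gene, reads whose position, moved 50 bp in the direction of the read, fell within 1000 bp of a start site (Mbd3) or 500 bp (Pol II) were counted. Reads at the same position and strand counted once. Where a gene had several start sites, the one with most Pol II RPM within 500 bp, summed over the Pol II libraries, was kept. RPM here divides by the reads counted, which were 1967130, 12667965, 3393057, 1564979, 8706329, 4349101 and 11171708 in the library order above. The GC content of the read bases was 44.9, 44.7 and 44.3% in the Pol II libraries. Background was taken from 85018 bins of 10 kb at least 10 kb from any start site, with at least 250 bases per kb seen in reads and without bins over 10 times the median bin. CpG classes used the bases seen in reads: high for a 500-bp window with observed over expected CpG above 0.6 and GC above 55%, low for none above 0.4, and intermediate otherwise. No class was given to 395 genes. No input library was used here, so enrichment is relative to distant bins of the same library. For GC matching, 1-kb background bins were grouped in steps of 2 GC points.

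The comparisons, the alternatives, the named-genes rule and the gene lists were fixed before the data were examined. Mbd3 was compared with the edgeR quasi-likelihood test on promoter counts, scaled by the library total, at an adjusted p of 0.05, over promoters with at least 10 reads in total that passed filterByExpr at a minimum count of 10. Only the wild-type pair gives the spread (1 residual degree of freedom), each knockdown library is assumed to vary like it, and this spread may be technical only. With all reads of the coverage tables counted, which keep identical sequences, 1709 promoters were tested by edgeR. It called 0 in either comparison, and 14 and 2 had an unadjusted p under 0.05. Pol II groups had 1 library each, so log2 ratios of RPM with a pseudocount of 1 were given with 95% exact conditional binomial intervals and no test, for promoters with at least 30 reads in both libraries together. Gene bodies were counted from 500 to 4000 bp after the start site, a departure from the plan to use gene ends, which were not used here. This window can run past the end of short genes. Background by distance from start sites and CpG classes from read bases also depart from the plan. Gene lists were set beside 10000 random lists of equal size matched on level in 20 bins. The lists were pluripotency, trophectoderm, primitive endoderm, early mesoderm and ectoderm, Polycomb-target developmental, methylated germline, imprinted, two-cell-stage, fibroblast, NuRD, esBAF, DNA methylation machinery, glycolysis and housekeeping, Myc and nucleolar, p53, interferon response, immediate early and heat shock, cell cycle, adult tissue, ribosomal protein and replication histone genes.

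Named genes followed a rule. For Mbd3 comparisons these were Mbd3, Tet1 and Smarca4, then the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with both wild-type libraries on the same side, filled by unadjusted p where fewer pass. For Pol II they were Mbd3 and Smarca4, then the 10 genes with the highest and the 10 with the lowest interval bound nearest to 0. For Mbd3 level they were the 10 genes with the highest mean RPM in wild type. Up to 4 members per list could be named, being the highest, the lowest and those with most reads. The Tet1 promoter was not analysed here. A ratio against 0 reads was given as a bound from a floor of 3 reads in that library, which leaves out counting error in wild type. Ratios of single Mbd3 promoters with intervals were taken to the pooled reads of both wild-type libraries. Those of classes and lists were taken to the mean of both.

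On simulated data with known changes of 50 promoters per size (17538 promoters, Tet1 comparison, no low-count filter), edgeR called 4% of those at a log2 change of -3, 4% at -2, 20% at 2 and 92% at 3, and 2 unchanged promoters. Decreases were mostly beyond its reach in that setting. The main test used 1592 filtered promoters with a larger fitted spread (common dispersion 0.249 against 0.0645 without the filter). These shares therefore do not give the power of the main test. Pol II intervals lay off 0 for 80, 40, 74 and 100% of promoters with simulated changes of -2, -1, 1 and 2 in the Mbd3 knockdown and for 84, 58, 80 and 100% in the Brg1 knockdown, and for 3.26 and 3.28% of unchanged promoters. Alternatives were TMM and background scaling, DESeq2, no low-count filter, other window widths, all reads counted, thinning to the shallowest library, each wild-type library left out, other pseudocounts and read minimums, median centring, and a split control. Added after the data were seen were GC-matched background, a background of 1-kb bins, lists matched on CpG class, and each wild-type library alone against Pol II. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.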

Results

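Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Mbd3 and RNA polymerase II (Pol II) in mouse embryonic stem (ES) cells. Mbd3 is a methyl-CpG-binding-domain protein and a subunit of the nucleosome remodelling and deacetylase (NuRD) complex. Mbd3 was mapped in wild-type cells (2 libraries), in Tet1 knockdown cells (1 library) and in Brg1 knockdown cells (1 library). Tet1 oxidises 5-methylcytosine to 5-hydroxymethylcytosine, and Brg1, encoded by Smarca4, is the ATPase of the esBAF remodelling complex. Pol II was mapped in cells transfected with esiRNA against EGFP as control, against Mbd3 and against Brg1, with 1 library each. The series sets Mbd3 binding in cells depleted of other chromatin regulators beside transcription in cells depleted of Mbd3 or Brg1. After each position and strand was counted once, the Mbd3 libraries held 1967130 (wild type 1), 12667965 (wild type 2), 3393057 (Tet1 knockdown) and 1564979 reads (Brg1 knockdown). The Pol II libraries held 8706329 (EGFP control), 4349101 (Mbd3 knockdown) and 11171708 reads (Brg1 knockdown). The median promoter held 3, 20, 2 and 1 reads in the Mbd3 libraries and 12, 6 and 14 reads in the Pol II libraries, so single promoters were measured with little precision in the smaller libraries. Intervals cover counting error only, and floors only that of the knockdown library.

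In both wild-type libraries Mbd3 ChIP reads were concentrated at CpG-rich promoters, relative to background not matched on GC content. Read density within 1 kb of the start site was 2.26 times background (95% Poisson interval 2.24 to 2.28) in wild type 1 and 2.07 times (2.06 to 2.08) in wild type 2 over 10552 promoters of the high CpG class. It was 1.38 times in both libraries over 3356 promoters of the intermediate class, and 1.10 and 1.03 times over 3394 CpG-poor promoters. Over all 17697 genes the values were 1.83 and 1.70. Promoters of developmental regulators known as Polycomb targets in ES cells, such as the Hox genes, stood at 2.66 and 3.22 times background, and those of early mesoderm and ectoderm genes at 3.73 and 2.64. Pluripotency gene promoters stood at 2.18 and 2.12 times background, promoters of genes silent outside adult tissues at 1.45 and 1.28, and replication-dependent histone genes at 0.607 and 1.33.

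The libraries also differed in base composition. The GC content of the read bases was 48.6% in wild type 1, 44.7% in wild type 2, 42.1% in the Tet1 knockdown and 43.4% in the Brg1 knockdown. Across high CpG promoters, reads rank-correlated with GC content at 0.480, 0.356, 0.0466 and -0.0238 in the same order. Against background windows of equal GC content, a comparison chosen after the data were seen, high CpG promoters stood at 0.846 times background in wild type 1 and at 1.14 times in wild type 2. The corresponding values were 0.510 in the Tet1 knockdown, 0.802 in the Brg1 knockdown and 2.24 in the Pol II control library. Above 64% GC, that background rests on 372 windows of 1 kb. At equal GC content the excess at high CpG promoters was thus absent in wild type 1 and smaller in wild type 2. Densities of the gene lists were not matched in this way. The wild-type pair rank-correlated across all promoters at 0.516, across high CpG promoters at 0.274, and at 0.127 once each of those promoters was divided by its GC-matched background.

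**Figure D1:**
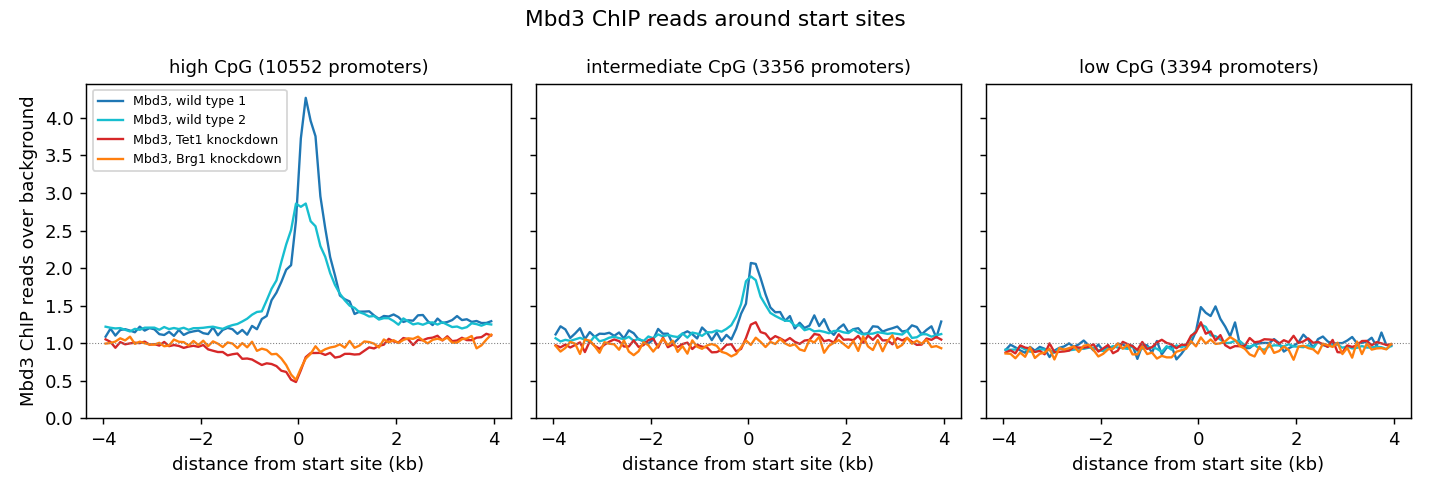
Mbd3 ChIP read density over background (vertical axis, dimensionless) against distance from the start site in kb, in 3 panels for the CpG classes, with 1 line per library. Without error bars, at high CpG promoters both wild-type lines peak at the start site (2.26 and 2.07 within 1 kb) while the knockdown lines dip there (0.745 for Tet1, 0.848 for Brg1).

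**Figure D2:**
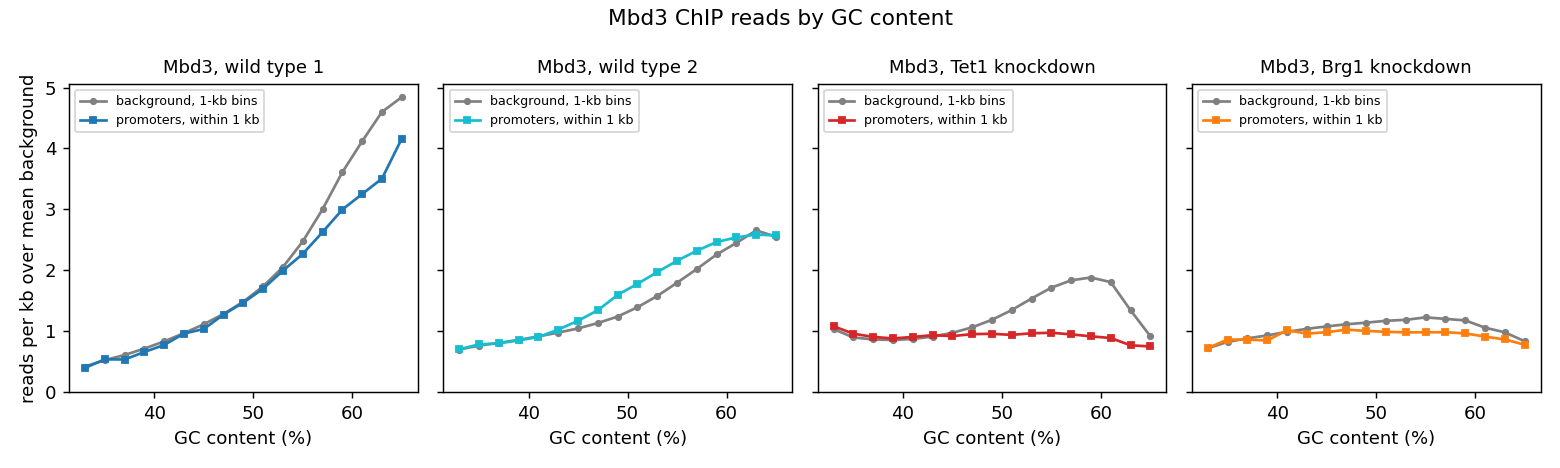
Reads per kb over the mean background against GC content in percent, with 1 panel per Mbd3 library, for promoters (squares) and for 1-kb background windows (circles). In wild type 1 the background climbs with GC content as steeply as the promoters do or more so, in wild type 2 the promoters lie above background of equal GC content over most of the upper range, and in the Tet1 knockdown they lie below it there.

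By mean RPM in wild type, Sfi1 had the highest Mbd3 level, with 52.9 ± 7.85 RPM (mean ± SD, n = 2). Its start site lies on chromosome 11 at 3093466. Sfi1 has copies elsewhere in the genome, and the Pol II libraries gave 45.6, 47.1 and 47.0 RPM in the same window, so its level is uncertain. Hoxd11 (chromosome 2, start site 74520450) followed with 7.48 ± 3.38, then Clcn4 with 6.28 ± 2.63 and Pou3f1, a POU-domain factor of the early epiblast and nervous system, with 6.13 ± 6.43. Ccdc116 (6.07 ± 5.79), Mafa (5.94 ± 3.82), Panx2 (5.93 ± 5.27), Fastk (5.84 ± 4.68), Aplp2 (5.80 ± 3.30) and Ndufa13 (5.71 ± 2.71) completed the highest 10. At Pou3f1 the spread between both libraries exceeded the mean. In wild type 2, Pou3f1, Ccdc116, Panx2 and Fastk held 20, 25, 28 and 32 reads, where the median promoter held 20. Their ranks thus rest on 21, 20, 19 and 18 reads in wild type 1.

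Mbd3 signal at CpG-rich promoters was lower in the Tet1 knockdown library than in either wild-type library. RPM summed over high CpG promoters gave a log2 ratio of -1.53 to the wild-type mean (counting interval -1.55 to -1.52), whereas the wild-type libraries differed from each other by -0.16. The ratio was -0.42 at intermediate and -0.04 at CpG-poor promoters, and -1.06 over all promoters. Density at high CpG promoters was 0.745 times background. The labels name no esiRNA target for the wild-type cells, and whether these were transfected is not clear from them. Against background of equal GC content the log2 ratio at high CpG promoters was -0.97.

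Polycomb-target developmental genes and genes of the DNA methylation machinery had low medians beside random lists in this library. Of 76 Polycomb-target members, 73 had lower Mbd3 signal than in wild type, with a pooled log2 ratio of -1.89 and a median of -1.82. That median was lower than in all 10000 random lists matched on level, and at percentile 0.270 when the lists were also matched on CpG class. The same list gave a median of 0.25 for wild type 2 over wild type 1, at percentile 100 of random lists, so the wild-type pair differed on it to the same extreme. Among its members, Hoxd11 had 135 reads in the wild-type libraries together and 1 read in the knockdown library (log2 ratio -4.97, interval -10.28 to -2.47), and Foxf1 had 101 and 8. Genes of the DNA methylation machinery, which include Dnmt1 (33 reads in wild type, 1 in the knockdown) and Gadd45b (52 and 2), had a pooled ratio of -2.03 and a median of -1.99 at percentile 0.290 (0.670 within CpG class). With members that had no knockdown reads set at the floor of 3 reads, the medians of both lists became -1.69 and -1.68. Replication-dependent histone genes had a pooled ratio of -1.51 and a median of -1.28, below all random lists. That median rests on the pseudocount, since 27 of 57 members had no knockdown reads, and it became -0.14 at the floor.

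Pooled log2 ratios in the Tet1 knockdown library were -1.80 for NuRD subunits, -1.77 for esBAF subunits, -1.83 for immediate early and heat shock genes, -1.70 for Myc and nucleolar genes and -1.69 for p53 targets. They were -1.44 for pluripotency genes, -1.48 for trophectoderm, -1.11 for primitive endoderm and -1.53 for early mesoderm and ectoderm genes. Ribosomal protein genes stood at -1.50, glycolysis and other housekeeping genes at -1.49 and cell cycle genes at -1.52. The smallest differences were at two-cell-stage genes (-0.19), genes silent outside adult tissues (-0.38), interferon response genes (-0.72), germline genes repressed by DNA methylation (-0.87), imprinted genes (-0.91) and fibroblast genes (-1.09). Only 30.8% of the interferon list, 16.7% of the two-cell list and 13.5% of the adult tissue list were high CpG promoters. Ribosomal protein genes, at percentile 0.210 of lists matched on level, were at 23.7 of lists matched also on CpG class.

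No single promoter passed the test between Tet1 knockdown and wild type. The edgeR quasi-likelihood test called 0 of 1592 promoters, with 22 at an unadjusted p under 0.05, all lower, and a smallest adjusted p of 0.670. DESeq2 also called 0, with 3 at an unadjusted p under 0.05, all higher in the knockdown. Without the low-count filter edgeR called 0 of 17580, with 3637 lower and 70 higher at an unadjusted p under 0.05 and a smallest adjusted p of 0.0679. Within 2 kb it called 0, with 1106 lower and 1 higher and a smallest adjusted p of 0.0938. With TMM scaling, which centres on the typical ratio of the tested promoters, their median log2 ratio moved from -1.88 to -0.15. The edgeR test then called 19 promoters, all higher in the knockdown, with 80 lower and 88 higher at an unadjusted p under 0.05. The shift removed was not shared by all promoters, since pooled ratios were -0.42 at intermediate and -0.04 at CpG-poor promoters. TMM scaling thus raised promoters of those classes. It adds the same amount to every ratio, so most lists would lie above 0 under it, while their percentiles among random lists were not recomputed. Of genes filled in by unadjusted p, which do not pass, the 10 lower ones were Hoxd11, Sfi1 and 8 genes with no knockdown reads. Bounds against the floor of 3 reads in the knockdown library leave out counting error in wild type. On this basis Aplp2 was at least 6.56-fold lower than the wild-type mean and at least 3.93-fold lower than wild type 2 alone. The same bounds were 6.30 and 3.39 for Eva1b, 5.54 and 1.87 for Bmf, 5.36 and 2.68 for Htr6, 5.29 and 4.82 for the Wnt ligand gene Wnt10b, 5.03 and 2.59 for AI661453, 5.01 and 3.12 for the homeobox gene Gsx1 and 4.99 and 3.66 for Col18a1. The bounds from the mean thus rest largely on 10 to 16 reads in wild type 1. The filter admits a promoter through a single library with enough reads, so some of these genes entered through wild type 1 alone. Bmf, for example, had 8.13 RPM there and 1.66 in wild type 2. This selection favours lower values in the knockdown, and the bounds and intervals do not allow for it. The tested promoters had a median log2 ratio of -1.88, against -1.14 over 17580 promoters without the filter. With counting error on both sides, upper ends of the intervals of the log2 ratio to the pooled wild-type reads ranged from -1.97 (Wnt10b) to -1.14 (Bmf). Sfi1 had a ratio with an interval of -1.34 to -0.67, above the median of the tested promoters, so its sign reversed with TMM scaling and in DESeq2, which remove that typical shift. The 10 genes with the largest increases also did not pass, though with TMM scaling all 10 did, and none lies in the high CpG class. Each of these had 13 to 15 reads in the knockdown and 1 to 5 in wild type 1, and lower RPM in every other Mbd3 library. They thus passed the filter through the knockdown reads and entered by the difference itself. Their intervals do not allow for this selection. As log2 ratios to the pooled wild-type reads, the 10 were 1700029I15Rik (2.0, interval 0.79 to 3.20), Fabp4 (1.81), Glis1 (1.72), Ppy (1.59, interval 0.50 to 2.65), Odf3l2 (1.49), Lime1 (1.22), Myo18a (1.21), Slurp2 (1.11), Shbg (1.11) and Man2c1 (1.06). At the Mbd3 gene itself (chromosome 10, start site 79862224) the libraries held 2 and 29 reads in wild type and 0 in the Tet1 knockdown. The interval of its log2 ratio to the pooled wild-type reads reached up to -0.88, and 2 reads in wild type 1 set no bound alone. Smarca4 held 1, 38 and 0 reads. Neither entered the test, and the Tet1 promoter was not analysed here.

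The Brg1 knockdown library also had lower Mbd3 signal at CpG-rich promoters. The pooled log2 ratio to wild type was -1.35 at high CpG promoters (interval -1.38 to -1.33), -0.52 at intermediate, -0.16 at CpG-poor and -1.01 at all promoters. Density at high CpG promoters was 0.848 times background. Against background of equal GC content the ratio at high CpG promoters was -0.31, and the wild-type pair had a spread of 0.31 (SD) on that scale.

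The esBAF subunit genes stood out, with 10 reads over 16 promoters against 533 in wild type and a pooled log2 ratio of -2.54. Their median was -3.38, at percentile 0.05 of random lists, but 11 members had no reads, and the median was -0.46 with these at the floor. It was -1.03, at percentile 15.2, within 2 kb of the start site. Genes of early mesoderm and ectoderm had a pooled ratio of -1.92 and a median of -1.90 (percentile 0.710, 1.83 within CpG class, -1.28 at the floor), with Zic2 at 81 wild-type reads and 1 knockdown read and Lhx2 at 63 and 0. Polycomb-target genes had a pooled ratio of -1.74 and a median of -1.55 (percentile 0.310, 4.95 within CpG class, -1.07 at the floor), with 75 of 76 members lower. Pooled ratios were -1.87 for Myc and nucleolar genes, -1.78 for cell cycle genes, -1.71 for glycolysis and housekeeping genes, -1.61 for p53 targets and -1.49 for immediate early and heat shock genes. They were -1.39 for pluripotency, -1.61 for trophectoderm, -1.36 for primitive endoderm, -1.29 for NuRD, -1.26 for imprinted and -1.0 for fibroblast genes. Ribosomal protein genes (-0.97), replication histones (-0.92), germline genes (-0.82), DNA methylation machinery (-0.81), interferon response (-0.70) and adult tissue genes (-0.64) lay nearest to wild type. The two-cell list, with 10 knockdown reads in all, stood at -1.0.

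No promoter passed the test between Brg1 knockdown and wild type either. The edgeR quasi-likelihood test called 0 of 1592, with 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.770. That promoter was lower. DESeq2 called 0, with 8 at an unadjusted p under 0.05, all higher, and edgeR with TMM scaling, which moved the median ratio from -2.09 to -0.58, called 0, with 126 lower and 66 higher. Without the low-count filter edgeR called 0, with 2518 lower and 58 higher at an unadjusted p under 0.05 and a smallest adjusted p of 0.281. Within 2 kb it called 0, with 705 lower and 4 higher and a smallest adjusted p of 0.0934. Of the 10 lower genes filled in by unadjusted p, 9 had no knockdown reads. Against the floor, again without wild-type counting error, Mafa was at least 3.10-fold lower than the wild-type mean and 1.69-fold lower than wild type 2 alone. The same bounds were 3.17 and 1.03 for Ccdc116, 3.10 and 1.15 for Panx2, 2.86 and 1.5 for Adrb1, 2.63 and 2.35 for Epb41l4a, 2.57 and 1.69 for Espn, 2.49 and 1.52 for Tgfb1 and 2.31 and 2.22 for Cldn7. Ydjc had 2.97 from the mean and 0.906 from wild type 2 alone, which does not show it lower there. The windows of Ccdc116 and Ydjc overlap. For these 9 genes, upper ends of the intervals of the log2 ratio to the pooled wild-type reads ranged from -0.94 (Epb41l4a) to -0.18 (Ydjc). Some of them passed the filter through wild type 1 alone, such as Ccdc116 with 10.2 RPM there and 1.97 in wild type 2. This favours lower values in the knockdown, which the bounds and intervals do not allow for. The median log2 ratio of the tested promoters was -2.09, against -1.14 without the filter. Sfi1 had a ratio of -0.90 (interval -1.39 to -0.44), and its sign again reversed where the typical shift of the tested promoters was removed. The 10 genes with the largest increases rested on 6 or 7 knockdown reads each. Their log2 ratios to the pooled wild-type reads ran from 1.51 (Lrrc23) to 3.49 (Olfr1134, interval 1.51 to 5.54). The others were Lce1h, Olfr450, Ugt3a1, Pclo, Cpa5, Scgb1b24, Ccl24 and Prss37. All had lower RPM in every other Mbd3 library, so they passed the filter through the knockdown reads and entered by the difference itself. Their intervals do not allow for this selection. Mbd3 held 1 read in this library (log2 ratio -1.73, interval -7.08 to 0.86) and Smarca4 held 0.

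Differences of both knockdown libraries from wild type were correlated across promoters. The Spearman correlation of the log2 ratios was 0.35 over 16734 promoters, with a covariance of 0.568. Simulated unchanged libraries that share the wild-type controls gave 0.22 and 0.186. With a different wild-type library as control of each knockdown, the correlation was 0.20 or 0.18 and the covariance 0.399 or 0.342, against 0.00508 and -0.00196 in the simulation. Promoters are not independent replicates, and the knockdown libraries also share the lower GC dependence of their reads.

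Pol II occupied CpG-rich promoters in all 3 libraries, at 3.79 times background within 500 bp of the start site in the EGFP control, 3.5 times in the Mbd3 knockdown and 3.72 times in the Brg1 knockdown. Within 1 kb, the window used for Mbd3, these values were 2.82, 2.63 and 2.82. The start site kept per gene was the one with most Pol II reads, which favours high Pol II densities. Also within 1 kb, replication histone genes had the highest density of the lists (14.8 times background in the control), followed by glycolysis and housekeeping genes in the control library (9.55). Polycomb-target genes lay at background (1.03, 1.00 and 1.07). Promoter density exceeded density from 500 to 4000 bp after the start site by 3.43, 3.20 and 3.19 times at the median of 1506 genes. The comparisons of Pol II set 1 library against 1, so they compare those libraries, not the conditions, and have no replicate check.

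In the Mbd3 knockdown library, the median Pol II ratios of ribosomal protein, glycolysis, cell cycle and Myc gene promoters lay below those of most matched random lists, and that of replication histone genes above. The median log2 ratio over 2565 promoters was -0.17, so groups are given beside random lists matched on level. Ribosomal protein genes had a median of -0.25 (percentile 0.905), with intervals below 0 at 10 of 72 promoters, Rpl22 among them at -1.21 (-2.41 to -0.26), and above 0 at none. Glycolysis and housekeeping genes had -0.33 (percentile 2.09), with 5 of 21 below and 1 above 0. Gapdh lay at -0.55 (-1.11 to -0.03), Gpi1 at -1.16 (-2.66 to -0.03) and Aldoa at 1.13 (0.32 to 2.03). Cell cycle genes had -0.39 (percentile 3.34), with 1 of 20 intervals above and 1 below 0. These were Cdc20 at 0.78 (0.00178 to 1.59) and Mcm7 of the replicative helicase at -1.06 (-2.05 to -0.24). Myc and nucleolar genes had -0.30 (percentile 5.01), with 4 of 22 intervals below and none above 0, Mycn lying at -1.28 (-2.92 to -0.09). Replication histone genes had 0.08 (percentile 99.8), with 28 members above and 23 below 0 and 4 of 51 intervals above 0 and none below. In the first 4 kb of the gene body their median was 0.23, above all random lists, with 12 of 52 above 0. Replication histone genes are near-identical and the assignment of reads between them was not tested, so single members are uncertain. In the gene body the medians were -0.31 for glycolysis and housekeeping genes (percentile 0.300), -0.39 for Myc and nucleolar genes (0.190), -0.14 for ribosomal protein genes (5.03) and -0.17 for cell cycle genes (21.8), so the last group was not low there.

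Pluripotency genes had a median of -0.06 (percentile 79.4) with 0 of 23 intervals off 0, but -0.23 (percentile 19.4) within 1 kb, so no direction is given for them. NuRD genes had 0.20 (percentile 88.4, 5 promoters), but -0.11 within 1 kb, esBAF genes -0.36 (14.9), DNA methylation genes -0.26 (37.6), p53 targets -0.09 (56.3) and immediate early genes -0.17 (36.1). The remaining lists had fewer than 5 promoters with 30 reads. Over gene bodies, DNA methylation genes had a median of -0.49 (percentile 4.36, 11 genes), esBAF genes -0.37 (11.3), NuRD genes -0.22 (22.7), pluripotency genes -0.10 (27.4), p53 targets 0.01 (49.7) and immediate early genes 0.04 (70.2). Medians were 0.00 for trophectoderm (percentile 91.2), -0.18 for early mesoderm and ectoderm (91.1), -0.04 for Polycomb targets (41.6), 0.04 for imprinted (65.6) and 0.17 for interferon response genes (63.9).

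Of the 2565 promoters, 36 had an interval above 0 and 161 below, 7.68% in all against 3.58% between simulated unchanged libraries. Centred on the median, the split was 96 above and 80 below. The genes with the lowest bounds were Pafah1b1, a regulator of dynein, at -2.99 (-6.45 to -1.41, 41 reads in the control and 2 in the knockdown), Ppp1r12a at -2.43 (-4.55 to -1.17), Haus1 at -2.46 (-5.92 to -0.82), Fem1b at -2.07, Gadd45g at -2.0, Nbeal1 at -2.14 (-4.72 to -0.69), Rif1, a replication timing factor, at -1.73 (-3.36 to -0.60), Epop at -1.66, Cdr2 at -1.79 and Cryz at -1.88. The highest were Ier3 at 1.63 (0.70 to 2.79), the metallothionein gene Mt1 at 1.60 (0.63 to 2.81), Zfyve26 at 1.37, Cdc45 at 1.3, Vcpkmt at 1.18, Brpf3 at 1.17, the Notch effector Hes1 at 1.17 (0.24 to 2.22), Srp68 at 1.17, Aldoa at 1.13 and H4c1 at 0.70. Over the gene body Ier3 (1.10, 0.14 to 2.20) and Mt1 (1.20, 0.36 to 2.16) were also above 0, while Srp68 was below it (-1.84, -4.43 to -0.35). All other body intervals of the lowest and highest genes included 0. Pol II at the Mbd3 promoter gave -0.52 (-1.62 to 0.44) and at Smarca4 -1.32 (-2.81 to -0.22). esiRNA acts on messenger RNA, so these reads do not check the knockdown.

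**Figure D3:**
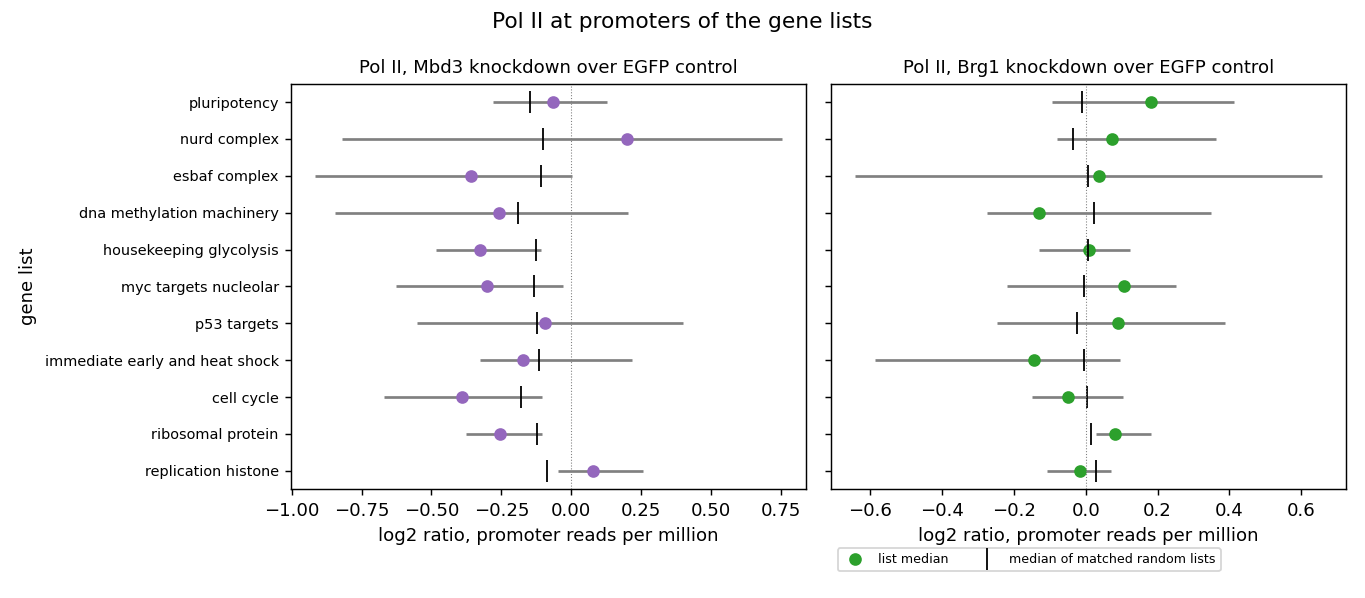
Median log2 ratio of promoter RPM (horizontal axis) for each gene list with at least 5 measured promoters, in the Mbd3 knockdown (left) and the Brg1 knockdown (right) over the EGFP control. Circles are list medians, grey bars the 95% range of medians from resampled members, black ticks the median of matched random lists, and ribosomal protein genes lie at -0.25 on the left and 0.08 on the right, and pluripotency genes at -0.06 and 0.18.

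In the Brg1 knockdown library, Pol II was higher over pluripotency genes than over most random lists of genes. Pluripotency genes had a promoter median of 0.18 (percentile 98.4, 24 genes) and a gene body median of 0.33 (percentile 99.8, 32 genes), with body intervals above 0 at 8 genes and below 0 at 1. Dppa2 lay at 1.20 (0.15 to 2.55) and Zfp42, also called Rex1, at 0.48 (-0.04 to 1.02), while Socs3, a STAT3 target, lay at -0.67 (-1.42 to 0.03). The 6 measured imprinted genes had 0.71, above nearly all random lists, with Peg10 at 1.25 (0.21 to 2.59), but their gene bodies had 0.19 (percentile 86.0, 18 genes). Immediate early and heat shock genes had -0.14 (percentile 9.81), with 3 of 17 intervals below 0 and none above, including Egr1 at -0.90 (-1.46 to -0.38), but their gene bodies had 0.10 (percentile 70.9). Ribosomal protein genes had 0.08 (percentile 95), Myc and nucleolar genes 0.11 (91.5) and p53 targets 0.09 (76.4). NuRD genes had 0.07 (69.2), esBAF genes 0.04 (59.3), DNA methylation genes -0.13 (18.4) but 0.12 within 1 kb (79.3), glycolysis and housekeeping genes 0.01 (51.4), cell cycle genes -0.05 (32.8, E2f1 at -1.12) and replication histones -0.02 (17.8). In the gene body window, which can run past the end of short genes, replication histones had -0.02 (percentile 0.430), with 6 of 56 intervals below 0 and none above. Myc and nucleolar genes had 0.26 there (97.6), p53 targets 0.22 (89.8), NuRD genes 0.19 (87.2), ribosomal protein genes 0.15 (76.0), cell cycle genes 0.06 (56.1), glycolysis and housekeeping genes 0.07 (31), DNA methylation genes -0.07 (24.6) and esBAF genes -0.13 (14.3). In gene bodies, trophectoderm genes had -0.32 (percentile 3.17, 14 genes), primitive endoderm -0.36 (7.86, 8 genes), adult tissue genes -0.20 (3.8), Polycomb targets -0.06 (24.1), early mesoderm and ectoderm 0.12 (84.6), germline 0.05 (63.6), fibroblast 0.09 (68.4) and interferon response genes 0.20 (93.4). The two-cell list had too few measured genes in either comparison.

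Of 4650 promoters, 166 had an interval above 0 and 209 below, 8.06% in all against 3.26% between simulated unchanged libraries, around a median of -0.01. The lowest were Chac1, a glutathione-degrading enzyme, at -2.37 (-3.85 to -1.40), Tulp3 at -2.55 (-4.53 to -1.40), the arginine synthesis enzyme Ass1 at -2.12, Stc2 at -1.86, Ier5l at -1.40, Actn1 at -1.69, cyclin D1 (Ccnd1) at -1.31 (-2.01 to -0.69), Cyb5r3 at -1.66, Exo5 at -1.48 and Ralgapa1 at -1.69. The highest were Tnfrsf25 at 2.22 (1.20 to 3.75), Wasf2 at 2.27, Mrpl36 at 1.80, Erf at 1.84, the esBAF subunit gene Arid1a at 1.35 (0.74 to 2.07), Atf6b at 1.95, Rpp40 at 1.70, Acer2 at 1.85, the meiotic recombinase Dmc1 at 1.55 and Tmem39b at 1.58. Except Arid1a (26 reads), the highest genes had 4 to 9 reads in the EGFP control. In the Mbd3 knockdown Tnfrsf25, Atf6b and Acer2 also lay above 0, Ccnd1 and Ralgapa1 below it, and the other intervals included 0. Whether the shared control accounts for this was not tested. Over the gene body Tnfrsf25, Wasf2, Erf and Arid1a lay above 0, Ass1 below it, and the other intervals included 0. Smarca4 itself lay at -0.64 (-1.41 to 0.07) at the promoter and Mbd3 at 0.36 (-0.26 to 1.02).

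The Pol II ratios of both knockdowns had a Spearman correlation of 0.32 across 2557 genes and a covariance of 0.0745. Both use the same control library, and simulated unchanged libraries gave 0.42 and 0.0794. With the reads of the control library split at random between the comparisons, the values were 0.05 and 0.0130, against 0.03 and 0.0102 in the simulation. A covariance shared by both knockdowns beyond that from the control was therefore not detectable at this depth.

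Mbd3 level in wild type increased with Pol II level across genes, while among high CpG genes the sign differed between the wild-type libraries. The Spearman correlation of mean wild-type Mbd3 reads with Pol II reads in the control library was 0.34 across 17697 genes, but -0.09 among high CpG genes, 0.23 among intermediate and 0.33 among CpG-poor genes. For wild type 1 and wild type 2 alone it was 0.21 and 0.45 across all genes, and -0.15 and 0.09 among high CpG genes. At equal GC content, with both proteins counted within 1 kb, it was -0.10 and 0.21 among high CpG genes. For the knockdown libraries across all genes it was -0.11 (Tet1) and 0.00344 (Brg1). Wild-type Mbd3 level had little relation to the Pol II ratio in the Mbd3 knockdown (-0.0572) or the Brg1 knockdown (-0.0344). In 4 groups of genes of rising Mbd3 level, the median Pol II ratio in the Mbd3 knockdown was -0.11, -0.19, -0.15 and -0.23. Genes are not independent replicates.

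**Figure D4:**
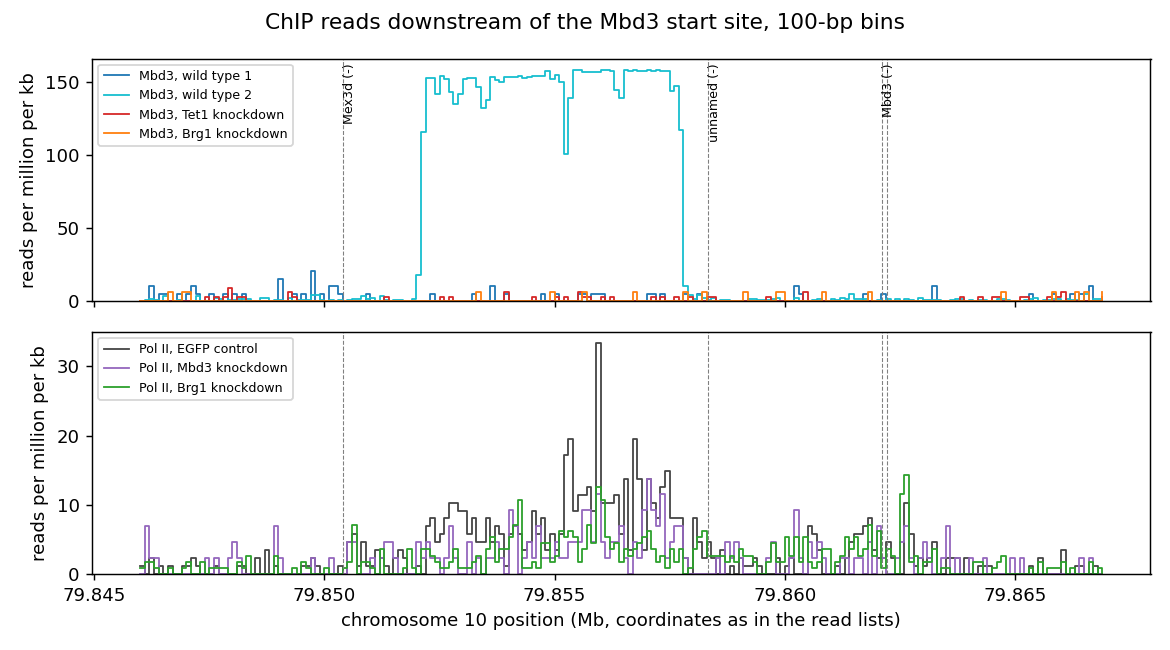
RPM per kb in 100-bp bins (vertical axes) along chromosome 10 around the Mbd3 start site (horizontal axis, Mb), for the Mbd3 libraries (top) and the Pol II libraries (bottom), with start sites as dashed lines and the strand in brackets. In wild type 2 a block of 5700 bp downstream of the start site stands at 149.5 RPM per kb, against 1.34 in wild type 1, 0.827 in the Tet1 knockdown and 0.448 in the Brg1 knockdown.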

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

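The tests of all patterns weighed here were chosen, or their bounds set, only after the results were seen. The split control was planned beforehand, and its bounds were set afterwards.

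A block of 5700 bp on chromosome 10, from 79852101 to 79857800, held 10797 reads in wild type 2, or 149.5 RPM per kb against 1.54 in its flanks. It lies outside the promoter windows of 1000 bp, 4.42 to 10.1 kb downstream of the Mbd3 start site, and holds no start site. Reads occupied 94.7% of its strand positions, so the density is a lower bound. Read density changed 28.5 times within 400 bp across the edges, consistent with extra copies of this DNA in the library, such as a plasmid or a construct. In wild type 1 the block stood at 0.877 times its flanks, which argues against Mbd3 binding shared by wild-type cells. Its source is not known from these data.

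The same block held 8.77 RPM per kb in the Pol II library of the EGFP control, 4.24 in the Mbd3 knockdown and 3.64 in the Brg1 knockdown, against 1.67, 1.42 and 1.78 in the flanks. In the coverage tables, which keep identical reads, stacks of 12859 reads over a single bin near Pou4f3 and of 4239 near Fbxo47 appeared in wild type 1. Start sites without a name, at least 5 kb from named ones (11026 sites), stood at 1.35 times background in wild type 1 and 1.28 in wild type 2, against 1.03 in the Tet1 knockdown and 0.966 in the Brg1 knockdown.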

How the results depend on the processing

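Each processing choice was changed on its own, except that DESeq2 brought its own scaling and the GC-matched edgeR test also left out the low-count filter, and settings said to be added were chosen after the data were seen. No paired analysis was possible because only the wild-type Mbd3 libraries carry replicate numbers and every other group has 1 library. Enrichment over all and over high CpG promoters within 500 bp was 2.24 and 2.88 in wild type 1, 1.98 and 2.48 in wild type 2, 0.833 and 0.700 in the Tet1 knockdown and 0.827 and 0.761 in the Brg1 knockdown. Within 2 kb it was 1.50 and 1.77, 1.44 and 1.69, 0.884 and 0.824, and 0.915 and 0.920 in the same order, since a narrower window holds less flank. With the added background of 1-kb bins it was 2.08 and 2.58, 1.86 and 2.27, 0.904 and 0.800, and 0.935 and 0.906. Thinned to the shallowest library, high CpG values were 2.27 and 2.08 in wild type and 0.740 in the Tet1 knockdown, and random thinning leaves the expected ratio in place by construction. With all reads it was 0.829 and 0.733 in the Tet1 and 0.846 and 0.818 in the Brg1 knockdown. There the background still used reads counted once per position, scaled to the library total, so promoters and background were not counted alike. The cause of these and the following moves was not tested unless stated. TMM scaling, which removes the typical shift of the tested promoters by construction, called 19 promoters in the Tet1 knockdown, and 0 were called with each other setting tried in either comparison. Pooled log2 ratios over all and high CpG promoters were -1.34 and -1.93 (Tet1) and -1.35 and -1.82 (Brg1) within 500 bp, -0.73 and -1.06 and -0.68 and -0.91 within 2 kb, and -0.63 and -0.97 and -0.22 and -0.31 at equal GC content (added). With either wild-type library left out, the high CpG ratio ranged from -1.61 to -1.45 (Tet1) and from -1.43 to -1.27 (Brg1). Sfi1 reversed to 0.62 with TMM and 0.62 in DESeq2 (Tet1) and to 0.42 and 0.47 (Brg1), since both remove the typical shift of the tested promoters. In the Pol II comparison of the Mbd3 knockdown, the median ratio was 0 when centred, by construction, -0.13 within 1 kb, -0.14 with a pseudocount of 5 and -0.081 with at least 100 reads. Intervals above and below 0 numbered 96 and 80 when centred, 88 and 258 within 1 kb, 207 and 450 with all reads and 4 and 7 with at least 100 reads, where fewer promoters entered. In the Brg1 knockdown the median was 0.038 with at least 100 reads, and the numbers were 327 and 354 within 1 kb, 552 and 597 with all reads and 19 and 14 with at least 100 reads. The Pol II ratios of both knockdowns had a Spearman correlation of 0.0533 and a covariance of 0.0130 with the control split. The Mbd3 ratios had correlations of 0.203 and 0.180 and covariances of 0.399 and 0.342 with different wild-type controls. With either wild-type library left out, the correlation of Mbd3 level with the Pol II ratio ranged from -0.0587 to -0.0389 (Mbd3 knockdown) and from -0.0362 to -0.00785 (Brg1 knockdown). Within 2 kb, list medians moved in the Tet1 knockdown to -1.43 (Polycomb targets), -1.37 (DNA methylation), -1.21 (Myc and nucleolar) and -1.43 (immediate early), and in the Brg1 knockdown to 0.40 (two-cell), -1.03 (esBAF) and -0.61 (ribosomal). Other list medians stayed within their resampling range in 58 cases. Counted per named gene and setting, direction and side of the threshold stayed in 172 cases in the Tet1 comparison, with 10 newly past it (TMM) and 2 reversed, and in 182 in the Brg1 comparison, with 2 reversed. Pol II ratios of named genes stayed within their interval in 109 cases and left it in 2 in the Mbd3 knockdown (110 and 1 in the Brg1 knockdown). At a median of 1 to 3 promoter reads in the smaller Mbd3 libraries, depth limits single promoters more than sums over classes.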

Other observations

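The tests of both patterns below had their bounds set only after the results were seen.

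Lower Mbd3 signal at CpG-rich promoters in the knockdown libraries may reflect library composition, depth or loss of binding. Wild type 1 had fewer reads than the Tet1 knockdown library and a density at high CpG promoters of 2.26 times background against an upper bound of 0.754, which argues against depth there, while for the Brg1 knockdown library, shallower than both, the upper counting bound of 0.862 at its own depth argues against counting error alone. At equal GC content the log2 ratio was -0.97 for the Tet1 knockdown, beyond 2 times the 0.308 (SD) of the wild-type pair. Matching on GC content thus did not remove the difference there. High CpG promoters of that library lay at 0.510 times GC-matched background, against 0.846 and 1.14 times in wild type. Density below background need not come from loss of binding, so the matching cannot exclude library composition as a cause. For the Brg1 knockdown the log2 ratio was -0.31 and GC bias remains open. Background of high GC content may include CpG islands missing from the start sites used, which would understate promoter density. High CpG promoters were ranked by reads over GC-matched expectation in either wild-type library. The highest 1055 were then set against the lowest 5275 in the other libraries. Ranked in wild type 2, the GC-matched density ratio of these groups was 1.27 (1.22 to 1.33) in the Tet1 and 1.13 (1.06 to 1.19) in the Brg1 knockdown. Wild type 1 gave 1.22 (1.18 to 1.27). Ranked in wild type 1, the ratio was 1.45 (1.40 to 1.51) and 1.25 (1.19 to 1.33) against 1.17 (1.15 to 1.19) in wild type 2, which runs against a loss. Pol II gave 1.66 and 0.831, so the ratio is not specific to Mbd3 and loss of binding remains open, as does the efficiency of each immunoprecipitation.

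The covariance of the Pol II ratios in both knockdowns dropped from 0.0745 to 0.0130 when the control reads were split between them. This is consistent with the shared control library as its main source, and no biological explanation was tested.

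At equal GC content, background bins with most CpG held 1.21 to 1.39 times the reads of those with fewest in wild type 2 over 4 ranges of GC content. The ratio was 1.09 to 1.16 in wild type 1, 0.930 to 1.19 in the Tet1 knockdown, 0.888 to 1.03 in the Brg1 knockdown and 1.09 to 1.15 in the Pol II control.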
